A study of Escherichia coli with 6 samples.

How the data were processed

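The data are 6 Agilent 2-colour arrays, 2 for each of 3 selections of a transposon-marked Escherichia coli library. Per the labels, genomic DNA was extracted, transposon insertions were amplified by ligation-mediated PCR, and the product was transcribed from a T7 promoter with a dye-labelled nucleotide. Per the labels, Cy5 held the glucose culture and Cy3 the selection culture on every array. Per the file headers, Agilent Feature Extraction 9.5 made the processed signals, which are intensity values on a linear scale, after background subtraction, multiplicative detrending and dye normalization by linear and LOWESS steps within the array. The deposited background-subtracted and mean signals are intensity values before those steps. Feature Extraction's log ratio is, per the file headers, the log10 of red over green processed signal, so its sign is opposite to the ratio used here. The flags for spots well above background, saturated spots and outliers are deposited as 0 or 1. The authors' value table holds log10 ratios that equal the arrays' own log ratios for every probe spotted once (tolerance 0.0001), with r of at least 0.998 over all probes. Its column medians were 0.0227 and 0.0222 for KDG, 0.0418 and 0.0192 for LB, and -0.0122 and -0.0148 for ellagic acid, so it is not centred. The filter behind its 3768 to 9936 empty values per array is not stated.

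Each array has 105072 spots, of which 103747 are not controls and carry 92794 probes of 60 bases. Control spots and outlier spots (29 to 79 per array) were left out, and saturated spots were kept. A log2 ratio of green over red processed signal was taken, spots of a probe were averaged, and each array was centred on the median of its probes, without loess because marked DNA can shift one way over much of a genome. The medians before centring were -0.06 and -0.06 for KDG, -0.12 and -0.05 for LB, and 0.05 and 0.06 for ellagic acid. A probe was kept if well above background in either channel on at least 2 arrays, which left 89290 probes. A gene's value is the mean of its kept probes, at least 2, and a window's value the mean of at least 5 kept probes in 10 kb. Of the 4132 gene identifiers of the array, 4126 matched the table of locus tags, which updated 483 symbols, and 6 kept the array's name; 4101 genes and 464 windows were tested. Coordinates are those of the array's probes, 1-based, and the genome version is not stated. In 83 genes at least 50.0% of probes held a word of 25 bases found in another probe position, and such probes were kept. Probes of a gene were averaged without regard to their disagreement, and the median over probes was run as an alternative.

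Median mean signals of the selection channel were 442 and 534 for KDG, 92.0 and 152 for LB, and 408 and 480 for ellagic acid, against 936 to 1117 in glucose. Feature Extraction multiplied the Cy3 signal of the LB arrays by a median of 19.4 and 17.3, and that of the other arrays by 2.56 to 3.55. Of the negative control spots, 0% to 2.00% were well above background. Of saturated spots there were at most 0.393% in any channel.

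Genes and windows were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, all 6 arrays in 1 model with a mean per selection, each mean against 0 and each pair of means against each other. The Benjamini-Hochberg adjusted p had to be under 0.05 over all genes or windows. The SE given with a value is that of this model, which shares 1 spread per gene among the selections. The SD of the difference between duplicates was 0.33 for LB, against 0.12 for KDG and 0.13 for ellagic acid. The SE and adjusted p thus tend to be too small for LB and too large for the other selections. Neighbouring windows are not independent. Where no probe of a gene was well above background in a channel on both arrays of a selection, a bound was computed from signals normalized per channel, against the lowest signal among probes well above background, and it is open to dye bias. Of the genes named in the text, wbbI, safA, ykfI, ymfA, yfjP, idnK, nanY, fimA and hsdS had no probe well above background in the LB channel, and idnK, sgcA and fimA none in the ellagic acid channel, so their values there have no fold. The glucose channel of those arrays was also below background for idnK beside LB and for fimA beside ellagic acid. Per the file headers, each of 3 slides holds the 2 arrays of 1 selection, so slide and selection cannot be told apart, and a fit with the slide as a block was not run.

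A set of 17 gene lists was fixed before the data were examined: idn genes, gluconate and Entner-Doudoroff genes, hexuronate catabolism, amino acid biosynthesis, nucleotide and vitamin biosynthesis, amino acid catabolism and gluconeogenesis, glucose uptake and glycolysis, TCA cycle and respiration, multidrug efflux, iron uptake, oxidative stress, lipopolysaccharide and O antigen, flagella and chemotaxis, fimbriae and curli, restriction and modification, loci damaged in K-12, and essential genes. A list's mean was tested with an exact two-sided rotation test: gene values were turned around the circular gene order through all 4101 offsets, which keeps the likeness of neighbours, and p-values were adjusted over 51 tests of lists by selections, and separately over 51 tests of differences. Camera of limma ran beside it with a preset correlation of 0.01 and with an estimated one. By rotation 0 of the 51 selection tests passed, and 13 had an unadjusted p under 0.05; camera passed 10 with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.835. Of the 51 tests of differences, 2 passed by rotation, 14 by camera with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.651). Camera compares a list with the other genes, so its direction can oppose the sign of a mean. The genes rfbC, wbbK, wbbL and ilvG of these lists had too few kept probes.

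The rule for named genes was also fixed before the data were examined. For each selection it took the 12 genes with the largest positive and the 12 with the largest negative mean among those past the threshold, with the same sign on both arrays, at least 3 kept probes and at most 3 genes from any 10 kb window. It took the 5 highest and 5 lowest windows, joined where adjacent, the 5 largest genes in each direction of each difference, up to 4 members of each list, all idn genes, and acrA, acrB and tolC. The reading that these members are those with the largest mean in the list's own selection, or over all selections for lists without one, was settled after values had been seen. Genes named outside the rule, which are waaL, waaA, htrL, ymfJ and genes that describe a region, were chosen after their values were seen.

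The steps were tested on simulated data of independent genes with the real genes' spread, equal in all selections. In the real data the SD of the difference between duplicates was 0.12 for KDG, 0.33 for LB and 0.13 for ellagic acid. The simulation therefore does not show how the test behaves with the unequal spread of these data. Of 50 genes shifted by 0.25, 0.5, 1 and 2 on the log2 scale, the test called 8, 41, 47 and 49 for KDG, 15, 40, 48 and 48 for LB, and 10, 39, 47 and 48 for ellagic acid, and of 3901 unchanged genes 11, 3 and 6. The rotation test gave p under 0.05 in 6.4% of 500 runs with scattered lists of 40 genes and 5.6% with adjacent ones when nothing was shifted. With scattered lists of 40 genes shifted by 1 SD it did so in 100%. That does not show its power for shorter or clustered lists or for smaller shifts. Alternatives planned before the data were examined were normexp with an offset of 50, normexp with loess, no centring, no filter on dim probes, only probes above background in both channels on all arrays, the median over probes, only the arrays compared, eBayes with trend and robust settings, the replicate number as a block, the authors' value table, leaving out each array, the mean of the other selections in place of 0, windows of 5 and 20 kb, and the median over a list. Linear dye scaling without LOWESS, with signals floored at 5, and centring on the median of essential genes were added after seeing the data.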

Results

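The series measured transposon footprints of an Escherichia coli library in which transposon-marked regions of the K-12 strain MG1655 were carried in another E. coli strain. The library was diluted 500-fold and grown for 16 h in minimal medium with glucose, in minimal medium with 5-keto-D-gluconate (KDG), in LB, a rich medium, or in glucose medium with ellagic acid, a plant polyphenol. DNA beside the transposons was amplified, transcribed with a dye and hybridised, so the method is meant to measure the amount of marked DNA at a probe's position and not the expression of a gene; signal from unmarked DNA was not measured apart. Each of 6 arrays compared a selection medium, in Cy3, with glucose medium, in Cy5, and each selection had 2 arrays. Values are log2 ratios of the selection signal to the glucose signal, so a positive value means more signal after the selection than after glucose. The glucose channel was well above background at 95.4% to 95.8% of probes on the 6 arrays. The selection channel was well above background at 94.0% and 94.8% of probes on the KDG arrays, 74.7% and 88.3% on the LB arrays, and 94.2% and 94.6% on the ellagic acid arrays. The 2 arrays of a selection correlated across 4101 genes, which are not independent replicates, at a Pearson r of 0.925 for KDG, 0.839 for LB and 0.782 for ellagic acid. The SD of the difference between a selection's 2 arrays was 0.12 for KDG, 0.33 for LB and 0.13 for ellagic acid. The labels do not state whether the duplicates were separate cultures, so the p-values may measure technical spread alone, and the number of arrays limits the precision. Dyes were not swapped, so a dye effect adds to every ratio against glucose.

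**Figure D1:**
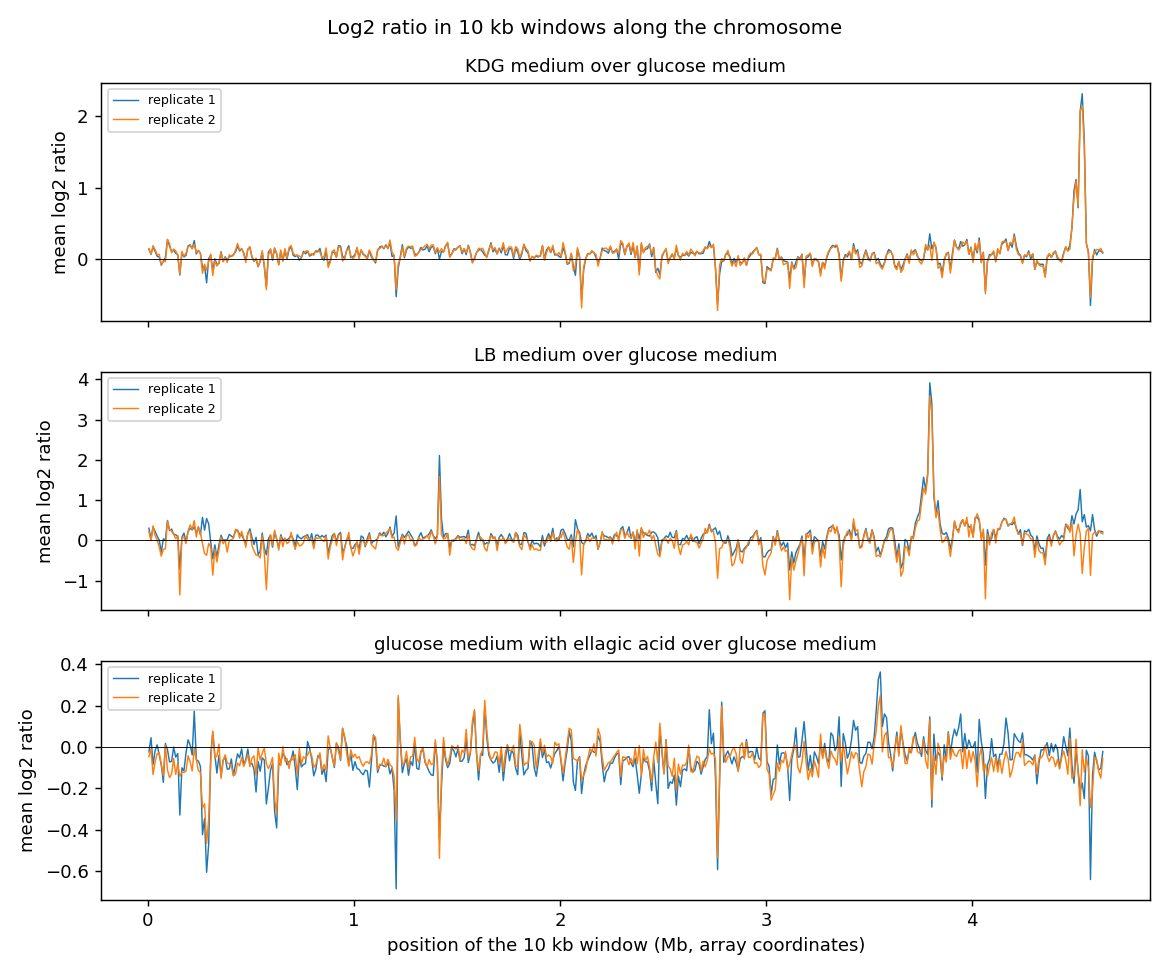
Mean log2 ratio of selection to glucose signal (y axis) in 10 kb windows along the array's chromosome coordinates (x axis, Mb), 1 line per array and 1 panel per selection. The highest windows are at 2.24 after KDG selection and 3.75 after LB selection, and the scale of the ellagic acid panel is smaller.

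The KDG arrays asked which marked K-12 regions became more or less frequent with 5-keto-D-gluconate as carbon source in place of glucose. The 30 kb from 4520001, which hold the fim genes of type 1 fimbriae, the nan genes of sialic acid use and the sgc and yjh genes, had a mean log2 ratio of 1.98 over 3 windows, with windows from 1.62 to 2.24 (n = 2 arrays). The region from 4490001 to 4510000, which starts within the idn genes of idonate and 5-keto-D-gluconate catabolism and ends within the fec genes of ferric citrate uptake, had a mean of 1.01. The gene fimA, for the main subunit of type 1 fimbriae, stood highest at 2.90 ± 0.28 (SE, n = 2; adjusted p = 0.0145). Its value rests on 5 of its 16 probes, and 40% of those readings were well above background in glucose, so its size and rank are not exact. The idn genes idnO, for 5-keto-D-gluconate reductase, and idnT, for the transporter, were higher at 1.33 ± 0.21 (adjusted p = 0.0191) and 1.33 ± 0.28 (adjusted p = 0.0299).

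Other genes of this part of the chromosome that were higher after KDG selection were yjhG (2.49), nanS, a sialic acid esterase (2.48), yjhI (2.46), ythA (2.40), fimD, the fimbrial usher (2.34), fimF, a minor fimbrial subunit (2.34), nanY (2.34), topAI (2.24), fimB, a recombinase of the fimbrial switch (2.19), sgcA (2.18) and yjhF (2.04). Their SE ran from 0.18 for sgcA to 0.36 for topAI and fimB, and their adjusted p from 0.0145 for yjhG to 0.021 for fimB. Lower genes included wbbI, a sugar transferase of the O antigen, at -1.84 ± 0.43 (SE; adjusted p = 0.0381), and rfbX, the O-antigen flippase, at -0.85 ± 0.20 (adjusted p = 0.0362). Both lie in the region from 2100001 to 2110000, which had a mean of -0.63. Other lower genes, which lie in prophages, were rrrD, a lysozyme gene, at -1.15 ± 0.20 (adjusted p = 0.0219; 0.17 against the mean of the other selections), ymfD at -1.06, ykfI at -1.04, rzoD at -1.03, the integrase genes intS at -0.97 and intA at -0.89, abpB at -0.94 and ycfK at -0.85. The genes ymfA (-0.97) and yfeS (-0.91) were also lower. In rzoD, 66.7% of probes held a word of 25 bases that occurs elsewhere on the array, and in ycfK 41.7%. Dim genes depended on the background correction: intS, ycfK, ykfI and ymfA had positive values after the normexp correction. Without the filter on dim probes, rfbX (0.39), intA (0.43), ymfD (0.0358), intS (0.15), ycfK (0.0261) and ymfA (0.36) had positive values. Further lower regions were 2980001 to 3000000 (mean -0.33), 3180001 to 3190000 (-0.37) and 4350001 to 4360000, with the cad genes of lysine decarboxylation (-0.25).

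**Figure D2:**
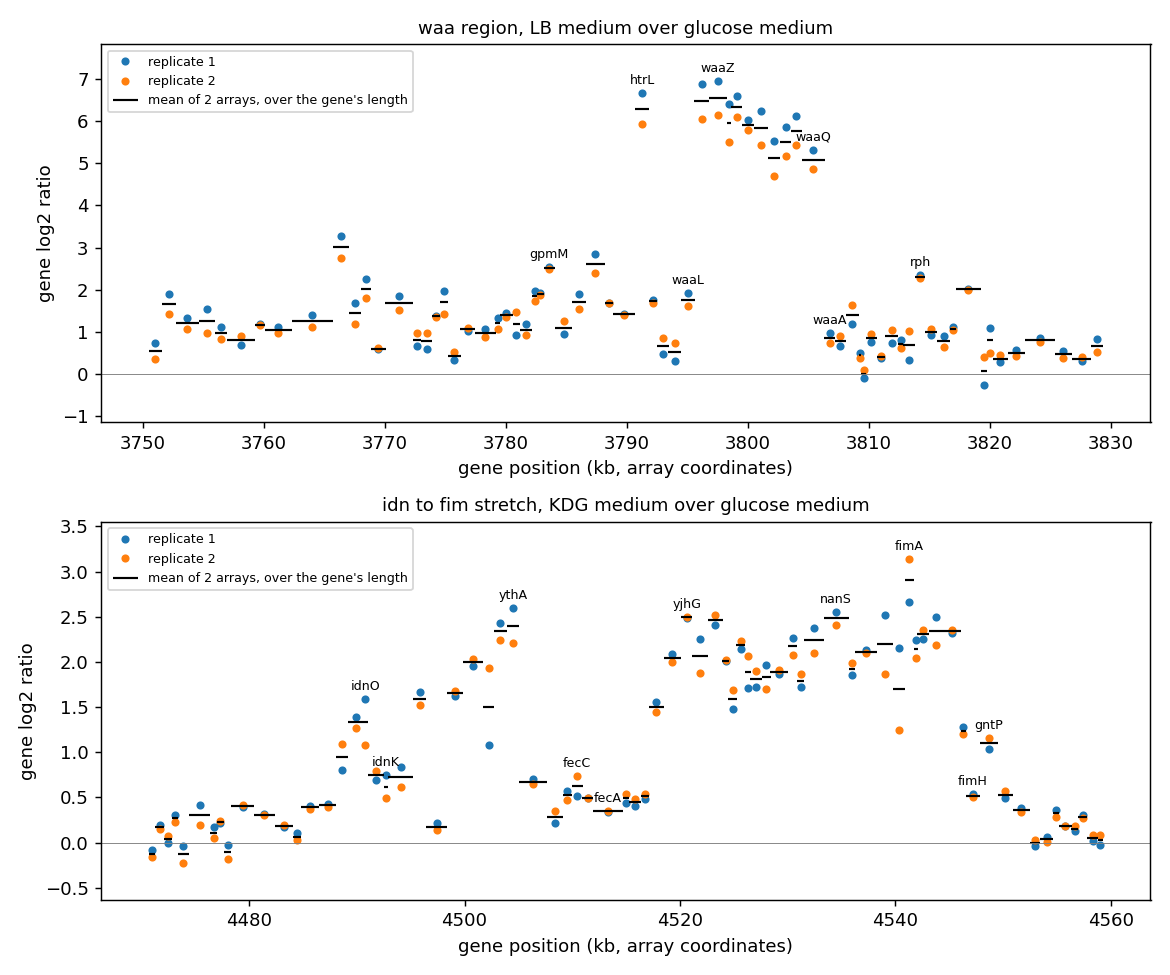
Gene log2 ratios (y axis) by gene position (x axis, kb) around the waa genes after LB selection and from the idn genes to the fim genes after KDG selection. Points are arrays and bars are means of the 2 arrays over each gene's length; the gene htrL stands at 6.30 beside the waa genes, and fimA at 2.90 is the highest gene of the KDG panel.

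The 5 genes of the idn list had a mean of 0.995 after KDG selection (SD of the 2 arrays 0.07), or 0.35 after normexp and loess. Of these, 2 were higher over all genes tested and 3 were higher adjusted over the list alone. The members idnR (0.95 ± 0.30 SE, adjusted p = 0.0717), idnD (0.74 ± 0.32, adjusted p = 0.141) and idnK (0.62 ± 0.29, adjusted p = 0.166) did not pass over all genes. The list's shift did not pass an exact two-sided rotation test along the chromosome (p = 0.00951, adjusted p = 0.138 over 51 tests), nor camera (adjusted p = 0.153, and adjusted p = 0.846 with an estimated correlation). After LB selection the same list had a mean of 0.82 (SD 0.85), with 3 genes higher, of which idnK had no probe well above background in either channel, but -0.01 after normexp and loess, 1.66 after normexp (rotation adjusted p = 0.0444) and 1.84 with linear dye scaling. Camera gave this list after LB an adjusted p of 0.944 with an estimated correlation, and the difference between KDG and LB, 0.18, did not pass the exact rotation test (adjusted p = 0.548). After ellagic acid selection the idn list had a mean of -0.25 (rotation adjusted p = 0.221). The difference between KDG and ellagic acid, 1.25, did not pass either (rotation adjusted p = 0.0959). Of 8 genes for gluconate use and the Entner-Doudoroff pathway, 2 were higher and 1 was lower (3 and 1 adjusted over the list alone), with a mean of 0.15 (rotation adjusted p = 0.583), or -0.02 when arrays were centred on essential genes. The members past the threshold were gntP, a gluconate transporter gene near the fim genes, at 1.10 ± 0.22 (-0.25 with only probes above background on every array), eda at 0.36 ± 0.07 and the repressor gene gntR at -0.59 ± 0.05. The gene edd, at 0.16 ± 0.04, passed over the list alone. Of 13 hexuronate genes, 3 were higher and 1 lower, also adjusted over the list alone (mean 0.08, median -0.01, rotation adjusted p = 0.915; mean -0.09 when centred on essential genes). They were uxuA (0.53), uxuB (0.36), uxaA (0.26) and kduI (-0.26). The gene uxuA starts in the same 10 kb window as fimA and gntP, and uxuB follows it by locus tag. The values of uxuA and uxuB thus cannot be told apart from the rise around the fim genes. Of 16 genes for fimbriae and curli, 9 were higher and 0 lower (9 and 2 adjusted over the list alone), with a mean of 1.06 (rotation adjusted p = 0.137; camera adjusted p = 0.206, and adjusted p = 0.898 with an estimated correlation), and the chaperone gene fimC stood at 2.31 ± 0.27. The mean of this list was 0.59 after normexp and loess (rotation adjusted p = 0.137) and 0.72 after normexp, where it passed (rotation adjusted p = 0.0444), as did the list's median of 0.88 (rotation adjusted p = 0.0415).

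In all, 1088 of 4101 genes passed limma's test after KDG selection, 841 higher and 247 lower, and 43 of them changed at least 2-fold. Of 464 windows, 218 passed, 198 higher and 20 lower. These counts rest on a spread shared by all 6 arrays, to which the LB arrays add most. With 1 KDG array left out, limma called 0 genes (805 without replicate 1 and 697 without replicate 2 at an unadjusted p under 0.05) and 0 windows (150 and 130 unadjusted). With either ellagic acid array left out it called 0 genes (1374 unadjusted), and with either LB array left out it called 2532 genes and 350 windows. Centring sets the direction of most small changes. The split was 421 higher and 494 lower genes without centring, 709 and 378 after normexp, and 121 and 731 with arrays centred on essential genes. For windows it was 89 and 79, 34 and 52, and 8 and 106. Of the 38 called genes named for KDG, 36 kept the call without centring, 33 when centred on essential genes, 31 after normexp, 27 without the filter on dim probes, 18 with the median over probes, 11 against the mean of the other selections and 0 with 1 KDG or ellagic acid array left out. Of the 38, 4 had the opposite sign after normexp, 6 without the filter and 3 against the mean of the other selections.

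The LB arrays asked which regions changed in frequency in rich medium. The region from 3780001 to 3810000, which holds the waa genes for the core of lipopolysaccharide, had a mean log2 ratio of 2.89 over 3 windows, from 1.64 to 3.75 (n = 2 arrays). Its highest genes by the naming rule were waaZ at 6.56 ± 0.19 (SE; 94.2-fold; adjusted p = 8.52e-05), waaU at 6.47 ± 0.20, waaJ at 6.35 ± 0.13, waaB at 5.84 ± 0.19, waaG at 5.77 ± 0.24 and waaP at 5.52 ± 0.27. In glucose 77.8% of the readings of waaZ were well above background, so its fold is not exact, and its log2 ratio was 3.02 after normexp and 2.21 after normexp and loess. Of genes beside these, htrL stood as high, at 6.30 ± 0.19, while waaL, for the O-antigen ligase, stood at 1.76 and waaA, for the enzyme that starts the core, at 0.86. The gene rfaH, which encodes the transcription factor of these operons and lies elsewhere at 4021951 to 4022910, was higher at 2.59 ± 0.04 (adjusted p = 1.43e-05).

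Further genes higher after LB selection were yibG (3.02), yicS (2.73), waaH, a sugar transferase of the core (2.61), gpmM, a phosphoglycerate mutase (2.52), and rph, the RNase PH gene beside pyrE (2.31). The window from 1410001 to 1420000, with recE, ydaG and ydaV of a prophage, had a mean of 1.85 ± 0.12 (SE), and that from 3760001 to 3770000 had 1.43 ± 0.06. The SD of the 2 LB arrays was 0.37 and 0.19 in these windows, so the SE from the shared spread is too small there. Lower genes included members of clusters for other fimbriae: yadM at -2.06 ± 0.21 (SE; adjusted p = 0.00122), yadC at -1.91, the usher gene htrE at -1.66, the chaperone gene yadV at -1.64 and yhcF at -1.82. The region from 150001 to 160000, which holds yadM, htrE and yadV, had a mean of -1.03. The prophage genes rrrD (-2.23 ± 0.20), borD (-1.82), yfdS (-1.80) and rzoD (-1.69), the transporter gene yihO (-1.83), casD of the CRISPR surveillance complex (-1.71 ± 0.09) and yjfZ (-1.68) were lower as well. Other lower regions were 3110001 to 3120000 with glcA and glcB (-1.10), 3360001 to 3370000 with nanT (-0.82), 3650001 to 3660000 with the acid resistance genes hdeA, hdeB and gadE (-0.79) and 4060001 to 4070000 with yihO (-1.03). The values of borD, rzoD, yadC, yadV, yfdS and yjfZ, dim genes after LB selection, were positive after the normexp correction. In 29 genes no probe was well above background in the LB channel on either array, and 13 of these are among the called genes, some of them as higher. By bounds, ymfJ, which has 2 kept probes and lies outside the naming rule, was at least 2.62-fold lower (adjusted p = 0.00229).

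Of 18 tested genes for lipopolysaccharide and O antigen, 11 were higher and 2 lower after LB selection, also adjusted over the list alone, with a mean of 2.16 (SD of the 2 arrays 0.51) and a median of 0.68. The exact rotation test gave p = 0.00146 (adjusted p = 0.0746, or 0.00622 with a mean of 1.68 after normexp and 0.0373 with a mean of 1.04 after normexp and loess), and camera an adjusted p of 0.103 (adjusted p = 0.846 with an estimated correlation). Of 64 genes for amino acid biosynthesis, 53 were higher and 3 lower (54 and 3 adjusted over the list alone), with a mean of 0.37 (SD 0.05), led by cysE (1.40 ± 0.05 SE), metE (0.78 ± 0.06), leuB (0.76 ± 0.04, but -0.0499 after normexp) and argH (0.76 ± 0.07). That shift passed camera with a preset correlation (adjusted p = 9.74e-07) but had an adjusted p of 0.835 with an estimated correlation, and it did not pass the exact rotation test (p = 0.0141, adjusted p = 0.138). By locus tag, cysE lies between yibG and gpmM, beside the waa genes. Its value cannot be told apart from the rise of that part of the chromosome. Of 40 genes for nucleotide and vitamin biosynthesis, 26 were higher and 0 lower (27 and 0 adjusted over the list alone), with a mean of 0.32 (rotation adjusted p = 0.138), or 0.07 when centred on essential genes and 0.115 after normexp, and thiG (1.04), panC (1.02), pyrE (0.68) and purD (0.68) led. For comparison, 43 of 66 essential genes were higher and 2 lower (44 and 2 adjusted over the list alone), with a mean of 0.25 (rotation adjusted p = 0.219), led by glyS (0.69), murE (0.67), lpxA (0.62) and gyrB (0.61). After KDG selection 30 genes of the amino acid list were higher and 1 lower (39 and 1 adjusted over the list alone), with a mean of 0.18, or 0.00652 when centred on essential genes (exact rotation test, adjusted p = 0.156, or 0.028 for the list's median; camera adjusted p = 0.0001, and adjusted p = 0.835 with an estimated correlation). The amino acid list's mean after LB was 0.12 when arrays were centred on those essential genes and 0.11 after normexp (rotation adjusted p = 0.754). Of the 4 loci known to be damaged in K-12, rph and pyrE were tested, and both were higher, also adjusted over the list alone. Their mean was 1.49, or 0.75 after normexp (rotation adjusted p = 0.138, or 0.351 after normexp). The genes ilvG and wbbL had too few kept probes. By locus tag, pyrE and rph are neighbours that lie near the waa genes. The 41 genes within 20 kb of the waa genes had a mean of 1.23. The values of rph and pyrE, also in the nucleotide list, cannot be told apart from that rise.

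After LB selection 2487 of 4101 genes passed limma's test, 1518 higher and 969 lower, and 193 changed at least 2-fold. Of 464 windows, 304 passed, 202 higher and 102 lower. The LB arrays differed more between duplicates than the others, and a fit of the 2 LB arrays alone called 454 genes and 159 windows. The split was 1123 higher and 1287 lower genes without centring and 536 and 1935 with arrays centred on essential genes. For windows it was 131 and 173 without centring, 126 and 158 after normexp, 272 and 76 after normexp and loess, and 38 and 301 when centred on essential genes.

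The ellagic acid arrays asked which regions changed when ellagic acid was added to glucose medium. The region from 610001 to 630000, with the ent and fep genes for the siderophore enterobactin, had a mean log2 ratio of -0.32 over 2 windows (n = 2 arrays). The enterobactin genes entB, entE and entF were lower at -0.68 ± 0.06 (SE; adjusted p = 0.036), -0.61 ± 0.08 (adjusted p = 0.049) and -0.50 ± 0.04 (adjusted p = 0.036). The cell division gene ftsP was lower at -1.17 ± 0.08 (adjusted p = 0.0323), which is 2.25-fold, and envZ, for the osmosensing kinase, at -0.79 ± 0.05 (adjusted p = 0.0323). The highest gene was hicA, for a toxin of a toxin-antitoxin pair, at 0.82 ± 0.08 (1.77-fold; adjusted p = 0.036).

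Other higher genes after ellagic acid selection were yqeK (0.68), safA, a connector of signalling systems (0.67), rzpQ (0.64), pheL, the leader peptide of pheA (0.63), yeeN (0.54), yqeJ (0.54), srlR, a repressor of sorbitol genes (0.50), yniD (0.50), zinT, a zinc-binding protein gene (0.49), cspI (0.48) and dgcT, for a diguanylate cyclase (0.47). Against the mean of the other selections hicA stood at -0.96 and pheL at -0.42, the opposite direction. Other lower genes were yeeR (-1.54), intE (-1.03), yfjP (-0.87), waaQ (-0.78), the sulfate transport gene cysU (-0.46), the division gene ftsN (-0.44) and the exonuclease gene recJ (-0.42). The values of yeeR, intE, yfjP and waaQ, all dim, were positive after the normexp correction. Higher regions were 3540001 to 3560000 with the mal and glp genes (mean 0.28), 1210001 to 1220000 (0.24), 1630001 to 1640000 (0.21) and 2780001 to 2790000 (0.21). Lower regions were 2560001 to 2570000 with the eut genes of ethanolamine use (-0.25) and 3020001 to 3040000 (-0.22).

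Of 33 genes for iron uptake, 0 were higher and 5 lower after ellagic acid selection (1 and 12 adjusted over the list alone), with a mean of -0.12, or -0.07 without centring, -0.06 when centred on essential genes and -0.04 with the median over probes (rotation adjusted p = 0.325; camera adjusted p = 0.067, and adjusted p = 0.835 with an estimated correlation). The gene feoB, of ferrous iron transport, stood at 0.52 ± 0.15 (SE; adjusted p = 0.11). Of 23 genes for multidrug efflux, 0 were higher and 0 lower by limma (0 and 2 adjusted over the list alone), with a mean of -0.05 that turned to 0.00485 without centring and 0.00974 when centred on essential genes (rotation adjusted p = 0.986). In that list acrD stood at -0.37 ± 0.06 (adjusted p = 0.0521), baeR at -0.25, emrB at -0.16, acrR at 0.14, and the pump genes acrA, acrB and tolC at -0.13, -0.03 and -0.13. Of 12 genes for oxidative stress, none passed over all genes or over the list alone (mean -0.03, or 0.03 both without centring and when centred on essential genes; rotation adjusted p = 0.849). Among them dps stood at -0.29, ahpF at -0.14, ahpC at 0.13 and katE at -0.11.

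Of the 24 called genes named for ellagic acid, 20 kept the call after normexp (the other 4 had the opposite sign), 9 in the authors' table and when centred on essential genes, 5 with the median over probes, 1 with linear dye scaling and 0 with 1 KDG or ellagic acid array left out. Limma called 82 of 4101 genes after ellagic acid selection, 43 higher and 39 lower, and 4 changed at least 2-fold, all of them lower. Of 464 windows, 54 passed, 6 higher and 48 lower. With either KDG array left out, limma called 0 genes (735 unadjusted) and 0 windows (104 unadjusted). It called 0 genes (303 without replicate 1 and 422 without replicate 2 unadjusted) and 0 windows (74 and 77 unadjusted) with 1 ellagic acid array left out, and 1564 genes and 283 windows with either LB array left out. The split was 128 higher and 34 lower genes without centring, 56 and 82 after normexp and loess, 12 and 2 when centred on essential genes, and 0 and 1 with linear dye scaling. For windows it was 15 and 8 without centring, 23 and 69 after normexp, 1 and 0 when centred on essential genes, and 0 and 2 with linear dye scaling.

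The selections were also compared with each other, since a dye effect common to all arrays cancels there. The Cy3 signal of the LB arrays was multiplied by a median of 19.4 and 17.3, against 2.56 to 3.55 on the others. A dye or background effect that varies with signal thus need not cancel in comparisons with LB. Between KDG and LB, fimD was 3.19 ± 0.36 higher after KDG (SE; adjusted p = 0.00916), nanS 3.14, nanC, a sialic acid porin gene, 2.91, yjhG 2.71 and sgcR 2.65. The waa genes lay lower after KDG, with waaU at -6.34 ± 0.29 (adjusted p = 0.000772), waaZ at -6.32, waaJ at -6.02, waaP at -5.79 and waaG at -5.78. Of 4101 genes, 819 differed, 436 higher after KDG and 383 lower. The split was 201 and 385 with linear dye scaling and 523 and 190 when centred on essential genes. The count was 39 with either KDG array left out, 1951 and 1860 without LB replicate 1 or 2, and 135 without either ellagic acid array.

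Between KDG and ellagic acid, sgcR was 2.99 ± 0.31 higher after KDG (SE; adjusted p = 0.0172), sgcQ 2.72, yjhI 2.65 and fimE, the other recombinase gene of the fimbrial switch, 2.64. The gene fimA is given no value here, since no probe of it was well above background in either channel of the ellagic acid arrays. Lower after KDG were ygeG at -1.15 ± 0.19 (adjusted p = 0.0196), ygeI at -1.05, safA at -1.05, yddJ at -1.02 and yqiH at -0.99. Of 4101 genes, 1134 differed, 891 higher after KDG and 243 lower, against 331 and 459 without centring and 72 and 477 when centred on essential genes. Limma called 0 genes with 1 KDG array left out (1055 and 1004 unadjusted) or 1 ellagic acid array left out (1083 and 1031 unadjusted), and 2486 with either LB array left out. Between LB and ellagic acid, waaY was 6.26 ± 0.31 higher after LB (adjusted p = 0.000673), waaU 6.20, waaZ 6.14, waaP 6.08 and waaB 6.03. Lower after LB were yrhB at -1.86 ± 0.17 (adjusted p = 0.00171), rrrD at -1.83, ylcG at -1.81, yadM at -1.75 and casD at -1.72. Of 4101 genes, 2254 differed, 1472 higher after LB and 782 lower, against 940 and 1103 without centring and 385 and 1521 when centred on essential genes; the count was 1088 and 989 without ellagic acid replicate 1 or 2.

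Of the genes called after KDG and after LB selection, 641 were higher in both, against 311 for independent lists, and 203 were lower in both, against 58.4. The lists share 1 spread per gene, so they are not independent, and their directions depend on centring. Centred on essential genes, limma called 121 genes higher and 731 lower after KDG, and 536 and 1935 after LB. The overlap was not counted under that centring. The log2 ratios of these selections correlated at r = 0.43 across genes, which are not independent replicates. With the same dye order, 4 genes were higher after both KDG and ellagic acid, against 8.82 for independent lists, and 6 lower, against 2.35 (r = 0.05), while of the 43 genes higher after ellagic acid 17 were lower after KDG, and of the 39 lower 7 were higher. After LB and ellagic acid 3 were higher in both, against 15.9, and 7 lower, against 9.22 (r = -0.07), while 30 of the 43 were lower after LB and 18 of the 39 were higher. For opposite directions no count for independent lists was computed. Among all 4101 genes, 247 were lower and 841 higher after KDG, and 969 lower and 1518 higher after LB. It is not stated whether the arrays shared 1 glucose DNA, which would add to an overlap.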

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

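The patterns weighed here had been seen when their tests were designed, but what each explanation predicted was written before the value of its test was computed. The rule that assigned genes to the waa core or to its flanks was changed from lying wholly inside to the gene's midpoint after the first values were seen.

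The lipopolysaccharide and O-antigen list stood out because it was the only list whose shift differed between selections in the rotation test of the difference itself: -2.48 for KDG minus LB (exact rotation test, adjusted p = 0.0124) and 2.33 for LB minus ellagic acid (exact rotation test, adjusted p = 0.0187). With an estimated correlation, camera gave an adjusted p of 0.651 for the first and 0.892 for the second. Of the list's 18 tested genes, 6 lie between waaQ and waaU (waaQ, waaG, waaP, waaY, waaZ and waaU), each at 5.09 or more after LB. All 10 genes of that stretch had a mean of 5.86, against 1.23 for 41 genes with midpoints in the 20 kb on either side, which ranged from -0.00393 to 6.30 for htrL. In glucose 74.85% of the probe readings of the 10 genes were well above background, against 98.9% for the 41. The mean of 5.86 is therefore not exact.

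The contrast of the waa genes with genes beside them, to which htrL is an exception, was weighed against 2 technical explanations. LOWESS is argued against, since linear dye scaling left 0.996 of the mean, 5.84. That scaling keeps the same background subtraction, whose effect on the waa genes was not weighed. The mean of the lipopolysaccharide and O-antigen list after LB was 2.16, against 1.68 after normexp and 1.04 after normexp and loess. The size of the waa rise thus depends on the processing. The glucose signal of the waa genes less that of the flanks was -3.1 on the log2 scale (-3.09 by the first membership rule). This met the prediction written for a floor of signal that compresses the ratios of the flanks. The LB signal was 7415 against 2560. Such a floor remains undecided, since these values set the levels of different probes side by side, and probes differ in response. A hypothesis is that K-12 waa genes were favoured in LB, and it could be tested by counting library members with and without the K-12 waa genes before and after growth in LB.

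The rise after KDG selection was uneven along the chromosome from the idn to the fim genes. Over 35 bins of 2 kb, the log2 ratio and the glucose signal had a Spearman rho of -0.703. This met the prediction written for a floor of signal in part of the stretch. The ratio contains the glucose signal, which could push rho down, though 66 other stretches of the same length had a median rho of -0.00042, and 2 of them were as negative (range -0.79 to 0.69). Since rho sets levels of different probes against each other, a floor stays undecided, and the height of fimA above idnO cannot be read as a stronger selection of fimA. Whether idn genes alone were selected, with fim genes carried along on the same marked DNA, is a hypothesis that library members with only 1 of these parts could test.

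Essential genes stood out because 99.9% of their probes (99.95) were well above background in the glucose channel, against 1% of negative control spots, although insertions within such genes would not be expected in a haploid cell. Their median glucose signal was only 0.11 below that of all genes (-0.111), which lies between the value predicted if signal comes from other DNA (0 or above) and the value predicted if it does not (more than 1 below). The test thus could not tell these apart, and it too compares levels of different probes. Signal may reach essential genes from insertions nearby, from the recipient's DNA or from labelling without insertions, and an array of the unmarked recipient could separate these.

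After normexp and loess, 69.3% of the genes called after KDG selection were higher, between the 60% or less predicted by an intensity trend and the 70% or more predicted without one, so that test could not tell.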

How the results depend on the processing

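Counts after every selection depended strongly on how the spread was shared, and those after KDG and ellagic acid also on how probes were summarised. Centring moved the split between higher and lower more than the KDG and LB gene counts. Counts of like size did not hold the same genes. Centred on essential genes, 368 of the 1088 KDG calls and 1505 of the 2487 LB calls kept their call and direction. Normexp called 1087 genes after KDG and 2986 after LB, but only 651 and 1287 of the main calls were among them in the same direction. The 2 arrays of a selection share a slide, it is not stated whether they are separate cultures, the dyes were not swapped, and leaving out 1 array assumes that the remaining lone array varies like the others. The slide as a block was not run. Linear dye scaling and centring on essential genes were chosen after seeing the data, and the other alternatives before the data were examined. Centring on essential genes moved the median of all genes by -0.17 for KDG, -0.25 for LB and 0.06 for ellagic acid, and the median over probes moved it by -0.10 for LB. The differences between replicates 1 and 2 correlated at r = 0.09, -0.06 and -0.28 between selections, so the replicate numbers do not pair. Most sign changes were in dim genes, and the cause was not tested.

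Of genes changed after KDG selection, 1088 became 2316 after normexp and loess, 209 with the median over probes (93 higher and 116 lower), 2375 with only the KDG arrays, 416 with the replicate number as a block, 114 against the mean of the other selections, and 0 to 2532 with 1 array left out. After LB, 2487 became 454 with only the LB arrays and 2033 to 2927 with 1 array left out, and the median over probes gave 841 higher and 1203 lower. After ellagic acid, 82 became 1012 after normexp, 138 after normexp and loess, 162 without centring, 15 without the filter on dim probes, 6 with only probes above background everywhere, 19 with the median over probes, 1235 with only the ellagic acid arrays, 150 with trend and robust settings, 1 with the replicate block, 15 from the authors' table, 2119 against the mean of the others, 1 with linear dye scaling, 14 centred on essential genes, and 0 to 1564 with 1 array left out. The 0 counts are limma's, with 303 to 1374 genes at an unadjusted p under 0.05.

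Of windows after KDG selection, 218 became 86 after normexp, 360 after normexp and loess, 102 with the median over probes, 388 with only the KDG arrays, 108 against the mean of the others, 425 with windows of 5 kb, 118 with 20 kb, 114 centred on essential genes, and 0 to 350 with 1 array left out. After LB, 304 became 159 with only the LB arrays, 634 with 5 kb, 160 with 20 kb, and 258 to 365 with 1 array left out. After ellagic acid, 54 became 92 after normexp, 126 after normexp and loess, 23 without centring, 4 without the filter, 6 with only probes above background everywhere, 14 with the median over probes, 193 with only the ellagic acid arrays, 116 with trend and robust settings, 4 with the replicate block, 10 from the authors' table, 298 against the mean of the others, 135 with 5 kb, 5 with 20 kb, 2 with linear dye scaling, 1 centred on essential genes, and 0 to 283 with 1 array left out (limma; 74 to 150 windows at an unadjusted p under 0.05 where KDG or ellagic acid counts were 0).

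Between KDG and LB, 819 genes became 2113 after normexp, 135 with only the arrays compared, 461 with the replicate block and 39 to 1951 with 1 array left out. Between KDG and ellagic acid, 1134 became 411 after normexp, 2166 after normexp and loess, 339 with the median over probes, 2486 with only the arrays compared, 627 with the replicate block, 549 centred on essential genes and 0 to 2486 with 1 array left out (limma; 1004 to 1083 unadjusted where 0). Between LB and ellagic acid, 2254 became 989 to 2909 with 1 array left out.

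The mean of the idn list after KDG selection stayed positive, from 0.35 to 1.11 over the alternatives and from 0.945 to 1.05 with 1 array left out. The amino acid list after LB was stronger as a median, 0.38 (exact rotation test, adjusted p = 0.0124; camera adjusted p = 0.835 with an estimated correlation), and ran from 0.34 to 0.41 with 1 array left out. The efflux list after ellagic acid turned to 0.00485 without centring, 0.0155 with the median over probes and 0.00974 centred on essential genes, and ran from -0.05 to -0.04 with 1 array left out. Of all 51 rotation tests of lists by selections, which include those of these lists, 0 passed. After normexp 7 passed, after normexp and loess 1, without the filter 1, and with only probes above background everywhere 1. Against the mean of the others 4 passed, with the median over a list 7, with linear dye scaling 1, and with 1 array left out 0 to 1.

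Of 140 named genes' results, 63 to 140 kept their call with 1 array left out, 90 of 113 with only probes above background everywhere, and 77 of 110 against the mean of the others. With only the LB arrays, 37 of the 48 named calls after LB held, and after normexp 37 held and 7 had the opposite sign. Leaving out 1 LB array takes the spread from the KDG and ellagic acid arrays alone. It therefore cannot test how these calls depend on the LB spread. With the replicate block, all 48 held after LB, 22 of 38 after KDG and 1 of 24 after ellagic acid. After normexp, signs turned after ellagic acid for acrA 0.00219, hsdM 0.48, intE 0.72, rfbA 0.40, rfbX 0.28, waaP 0.57, waaQ 0.25, yeeR 0.53, yfjP 0.81, and after LB for borD 0.82, hsdS 1.52, leuB -0.0499, rzoD 0.51, yadC 0.0599, yadV 0.33, yfdS 0.22, yjfZ 0.48, and after KDG for intS 0.0968, ycfK 0.21, ykfI 0.32, ymfA 0.0504, and for the LB minus ellagic acid value of ylcG 0.28. Without the filter on dim probes, signs turned after ellagic acid for hsdM 0.0362, rfbA 0.15, rfbX 0.39, waaP 0.31, yeeR 0.0539, yfjP 0.45, and after LB for hsdS 0.59, and after KDG for intA 0.43, intS 0.15, rfbX 0.39, ycfK 0.0261, ymfA 0.36, ymfD 0.0358. With only probes above background everywhere, signs turned after KDG for gntP -0.25, and after ellagic acid for rfbX 0.13, yeeR 0.17. Against the mean of the other selections, signs turned after ellagic acid for acrB 0.0881, dps 0.29, hicA -0.96, pheL -0.42, rfbA 0.25, and after KDG for idnK -0.15, kduI 0.14, manY 0.0474, rrrD 0.17. With the median over probes, signs turned after ellagic acid for acrB 0.00078, dps 0.0579, tolC 0.0394, and after KDG for edd -0.0192. Without centring, signs turned after ellagic acid for acrB 0.0252. Centred on essential genes, signs turned after ellagic acid for acrB 0.0301, and after KDG for edd -0.0061. With linear dye scaling, signs turned after LB for hsdS 0.24. Without ellagic acid replicate 2, signs turned after ellagic acid for acrB 0.0248, which stood at -0.0796 without replicate 1.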

Other observations

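Genes for respiration and motility were among those higher after LB selection. Of 41 genes for the TCA cycle and respiration, 27 were higher and 0 lower (27 and 1 adjusted over the list alone), with a mean of 0.27 that was 0.01 when centred on essential genes (rotation adjusted p = 0.325; camera adjusted p = 0.00764, and adjusted p = 0.835 with an estimated correlation). The ATP synthase genes atpF, atpE and atpC stood at 0.89 ± 0.06, 0.86 ± 0.15 and 0.76 ± 0.07 (SE, n = 2 arrays), and nuoB of complex I at 0.62 ± 0.12. Of 47 genes for flagella and chemotaxis, 26 were higher and 3 lower, also adjusted over the list alone, with a mean of 0.20 that turned to -0.05 when centred on essential genes (rotation adjusted p = 0.583). The flagellar genes fliL, fliP and fliQ stood at 1.08, 1.02 and 0.82, and after KDG selection the master regulator gene flhC stood at 0.61. Of 31 genes for amino acid catabolism and gluconeogenesis, 10 were higher and 11 lower after LB (11 and 11 adjusted over the list alone; mean -0.04, rotation adjusted p = 0.63). Among them tnaB and tnaA, for tryptophan uptake and breakdown, fell by 1.13 and 0.96, tdcB was lower at -0.66, and the malate synthase gene aceB was higher at 0.80.

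Of 11 genes for glucose uptake and glycolysis, 3 were higher and 1 lower after KDG selection, also adjusted over the list alone, with a mean of 0.07 that turned to -0.10 when centred on essential genes (rotation adjusted p = 0.945; camera's direction was down). The phosphotransferase genes ptsH and ptsG were higher at 0.49 and 0.24, manY was lower at -0.25, and manX, at 0.18, did not pass. Of 7 restriction and modification genes, none passed after KDG selection over all genes or over the list alone (mean -0.40, but 0.21 after normexp; rotation adjusted p = 0.138), and mcrB stood at -1.05 (adjusted p = 0.0524). In that list mcrA was higher after LB at 2.09 ± 0.14 (SE, n = 2 arrays; adjusted p = 0.000554), while hsdM after ellagic acid (-0.67, but 0.48 after normexp) did not pass. The lipopolysaccharide list had 0 genes higher and 4 lower after KDG selection, also adjusted over the list alone, with a mean of -0.32 that turned to 0.19 after normexp (rotation adjusted p = 0.138). Its members rfbX, waaP and rfbA stood at -0.80, -0.56 and -0.48 after ellagic acid selection, and none of these 3 passed. After normexp they stood at 0.28, 0.57 and 0.40, and the list's mean after ellagic acid was 0.41 (exact rotation test, adjusted p = 0.00622), against -0.17 without normexp (adjusted p = 0.219, and camera adjusted p = 0.978 with an estimated correlation).

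A list of prophage genes, drawn up after the values were seen and not checked against a reference, matched 106 tested genes. In glucose 90.6% of their probes were well above background, against 98.9% for all genes, and some dim genes changed sign with the background correction. Of these genes, 12 were lower and 5 higher after KDG selection, 27 lower and 27 higher after LB selection, and 3 lower and 3 higher after ellagic acid selection. Of all 4101 genes, 247 were lower and 841 higher after KDG, and 969 lower and 1518 higher after LB.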
